A study of Halobacterium salinarum NRC-1 with 36 samples.

How the data were processed

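The series holds 36 dual-colour arrays of Halobacterium NRC-1 total RNA, 2 for each of 18 time points in darkness, each against a standard mid-log reference. Per the labels, the culture was grown at 42 °C and entrained for 72 h with 12 h of light, at 150 µE, and 12 h of darkness, and the 2 arrays of a time point are dye flips. For each array the authors deposited a spot quantification export with the mean intensity of each spot and the median intensity of its local background, for each dye at a high and a low scan setting, as scanner intensity on a linear scale without normalization. The same deposited export gives a confidence score from 0 to 100 per spot, which fell below 100 where the spot was saturated. The quantification software is not stated.

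The authors also deposited a value table with a log10 ratio of Alexa 532 over Alexa 647 for each spot, not turned for the dye flip and not centred. The median of a column of this table lay between 0.009 and 0.265 and its standard deviation between 0.11 and 0.343. How its background and scan settings were treated is not stated. The order of its spots was settled from the values: across spots, its correlation with the log ratio of the exported intensities was 0.83 to 0.994 when spots were taken in the order of the slide and 0.118 to 0.368 in the order of the exported file. In 30 arrays the table leaves spots blank.

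Log ratios were built from the scanner exports. The spot mean at the high scan setting was used, and a spot saturated at that setting took its low scan signal, scaled per array and dye by the median ratio of both settings over unsaturated spots with a low scan signal above 500. The scale factor lay between 11.1 and 28 for Alexa 647 and between 6.88 and 11.7 for Alexa 532. Between 171 and 830 spots per array were saturated in Alexa 647 and between 87 and 397 in Alexa 532. This use of the low scan was chosen after the values, and after counts with saturated spots left out, had been seen. Background was corrected with limma's normexp method and an offset of 50, and each array was normalized by loess over the whole array. Ratios were turned to sample over reference, on the log2 scale, and the 4 spots of a probe were averaged.

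Each array holds 10752 spots, or 2688 probes. The 276 probes with any spot blank in the authors' table on all 30 arrays with blanks were left out. This left 2412 probes, and the choice too was made after the data were seen. A table with the platform pairs 532 spots, 4 for each of 133 genes, with symbols. All 133 symbols were found in an annotation of strain 91-R6 (assembly ASM479960v1), which is not the strain measured, so it was used only for which genes neighbour each other and no coordinates are given. The files do not pair the other 2279 probes with genes. Of the named genes, 38 had a saturated spot on any array and 5 on all arrays, 11 lay above background in the sample channel on fewer than 18 of the 36 arrays, and 2 did so on no array of a cycle.

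The mean of the 2 dye-flip arrays gave 1 value per time point, so that models had 18 values per gene. Models were fitted with limma's lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg over all 2412 probes with a threshold of 0.05. The 24 h course was tested by a moderated F-test of its cosine and sine with linear time as a covariate. The first and second 12 h of a cycle were compared with linear time as a covariate, and cycles with the 24 h terms as covariates. A change of the 24 h course between cycles was tested by an F-test of 4 interaction terms. Variation between time points was tested over 36 arrays with a dye term. The 24 h test was repeated at periods from 12 to 36 h in steps of 2 h. Residual degrees of freedom came from successive time points of a single culture series, which are not independent cultures and may be correlated in time.

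Gene lists were fixed as patterns on gene symbols and tested with camera, two-sided, with its preset correlation and with an estimated correlation, adjusted over the 11 lists with at least 4 measured members. These were opsins with their activator bat, DNA repair, the tricarboxylic acid cycle, sugar metabolism, chaperones and proteases, chemotaxis transducers, replication, cobalamin, purines and pyrimidines, amino acid synthesis and tRNA synthetases, with gatA and gatC among the last by the pattern as fixed. The genes glmS and panB matched a pattern without belonging to its function and were taken out by hand. The transducer genes htr1 and htr2 fell in the chemotaxis list by their symbols. Of the 32 lists, 11 had no member among the genes with a symbol, though their genes may be among the probes without one. Another 4 needed product names or locus tags, which the files do not give. None of these lists was analysed. The remaining lists had fewer than 4 members. Shared peak times were tested by the mean resultant length against 10000 random lists of the same size, one-sided.

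The comparisons, the gene lists, most of the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the genes past the threshold with the largest change or, where no named gene passed, the 5 with the smallest p, together with hop, bat, sop1, sop2, htr1 and htr2 in every comparison and up to 4 members of a list with the smallest p. Of these, only the 2 with the smallest p per list were carried through the alternatives. At most 2 probes without a symbol that rose and 2 that fell are named.

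The scripts were tested on simulated data, with 50 changed probes of each of 4 sizes among 2412 in the same run. The spread of each probe was its residual spread, drawn independently for each probe and value. For the models over time point means it was taken around the fit with interaction terms. The larger changes eased the adjusted threshold for the smaller ones, so the shares do not give the power where few probes change. The shares recovered stand beside their comparisons in the results. They were 0.1, 0.7, 0.94 and 1 at log2 sizes of 0.25, 0.50, 1 and 2 for cycle 2 against cycle 1, and 0.12, 0.66, 0.92 and 1 for cycle 3 against cycle 2. For variation between time points they were 0.36, 0.72, 1 and 1. Between 6 and 13 of the unchanged probes were called per comparison. When the background-corrected sample signal of 100 brighter probes was raised 2-fold on the arrays of cycle 3 before normalization, the median change recovered was 0.75 (log2) and a share of 0.91 was called. For 100 probes raised 4-fold it was 1.68, and all were called.

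Alternatives to the background correction, the within-array normalization, the source of the values, the treatment of saturated, blank and dim spots, the averaging of dye-flip arrays, the array number range, the eBayes prior, the covariates and the period were tried, each replicate and each time point was left out in turn, and time points were regrouped at random in 100 groupings. Ranges of array numbers are runs without a gap over 10. The software was R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package (1.17.8), and Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.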

Results

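Transcript levels were measured in Halobacterium NRC-1, a salt-loving archaeon that carries light-driven ion pumps and light-sensing rhodopsins. A culture had been entrained for 72 h in alternating 12 h of light and 12 h of darkness at 42 °C and was then sampled in darkness. RNA came from 18 time points between 0 and 68.5 h after entrainment, and every sample was compared with the same mid-log reference RNA on 2 dual-colour arrays. Replicate 1 carried the sample in Alexa 532 and replicate 2 carried it in Alexa 647, which gave 36 arrays. These dye-flip arrays repeated the labelling and not the culture, so each gene had 18 values from a single culture series. The time unit was taken from the sample titles, in hours, since a growth description in the labels calls the same numbers minutes.

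The time points fell into 3 cycles of 6, from 0 to 20 h, from 24 to 44 h and from 48 to 68.5 h. Counted within cycles, 9 time points lay in the first 12 h and 9 in the second 12 h, and the labels do not say which of these matched the former light phase. Each array held 10752 spots, 4 for each of 2688 probes, and 2412 probes were analysed. The files pair 133 of these with a gene symbol, and the other 2279 are known only by their spot number in the value table. Among the genes of light response, hop (halorhodopsin), sop1 and sop2 (sensory rhodopsins), htr1 and htr2 (their transducers) and bat (the bacterio-opsin activator) were measured. The genes bop, brp, phr1 and phr2 are not among the symbols, so any probes for them could not be identified.

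Signal over background differed between arrays. In the Alexa 647 channel 60.4% to 99.8% of probes lay above background, with a median of 92.8%, and in the Alexa 532 channel 28.9% to 96.2% did, with a median of 62.8%. Across all probes, which are not independent replicates, the change at a time point measured on replicate 1 arrays had a correlation of -0.13 to 0.37 with that on replicate 2 arrays. In the brightest 25% of the probes it lay between 0.11 and 0.736, with a median of 0.454. For arrays of different time points it lay between -0.688 and 0.673, with a median of -0.035. The number of arrays limits the precision of every value below.

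The first comparison asked which genes kept a component with the 24 h period of the entrainment while the culture stayed in darkness. No gene did so past the threshold. Halorhodopsin, the sensory rhodopsins, their transducers and bat had no 24 h course past the threshold either. The named genes that came closest to a 24 h course were tmk (thymidylate kinase), aroC (chorismate synthase), thiC (thiamine synthesis), lysS (lysyl-tRNA synthetase) and hisB (histidine synthesis), with peaks spread over the cycle.

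By limma's moderated F-test with linear time as a covariate, 0 of 2412 probes passed an adjusted p of 0.05, and 80 had an unadjusted p under 0.05 where 120.6 would be reached by chance. The smallest adjusted p was 0.173 over all probes and 0.993 over the 133 named genes. Fitted amplitudes were 0.26 ± 0.08 (log2, SE, n = 18 time points) for tmk with a peak at 7.07 h and 0.20 ± 0.06 for aroC with a peak at 20.3 h. They were 0.16 ± 0.05 for thiC with a peak at 1.35 h, 0.28 ± 0.09 for lysS at 16.8 h and 0.19 ± 0.07 for hisB at 15.7 h, each with an adjusted p of 0.993. The sample signal of tmk lay above background on 12 of 36 arrays.

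Among the light genes, the amplitude of hop was 0.13 ± 0.09, with an upper 95% bound of 0.31, and that of bat was 0.06 ± 0.12, with an upper bound of 0.31. The amplitude of sop1 was 0.06 ± 0.05, that of sop2 0.03 ± 0.04, that of htr1 0.11 ± 0.05 and that of htr2 0.03 ± 0.07. The median amplitude over all probes was 0.10. In data simulated with the residual spread, the same test recovered a share of 0.6 of 50 probes with an amplitude of 0.25. The share was 0.88 with 0.50, and all probes with amplitudes of 1 or 2 were recovered. Probes of all these sizes changed in the same run, which eases the adjusted threshold, so these shares do not measure the power behind the absence of calls here.

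**Figure D1:**
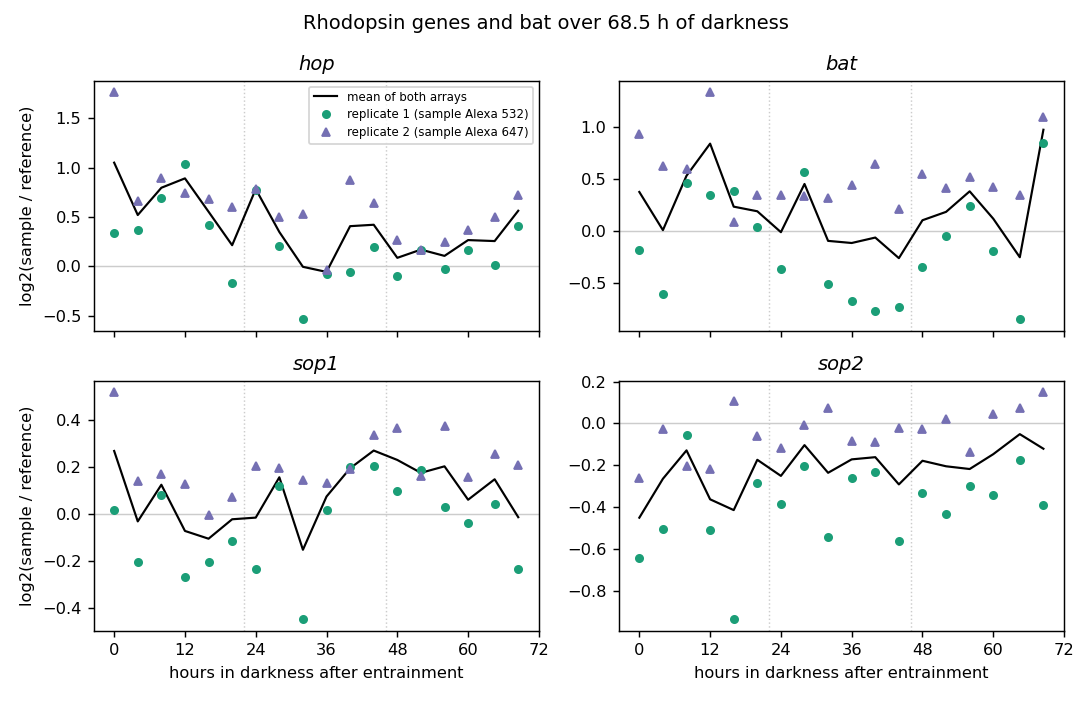
The log2 ratio of sample over reference (vertical axes) against hours in darkness after entrainment (horizontal axes) for hop, bat, sop1 and sop2, with replicate 1 and replicate 2 arrays as separate points and their mean as a line. The mean of hop runs from 1.05 at 0 h to -0.06 at 36 h, and none of the 4 genes repeats its course every 24 h past the threshold.

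Other periods served as a background for the 24 h count. None of the 13 periods scanned between 12 and 36 h gave a probe past the threshold by limma's F-test. The 24 h period gave 80 probes at an unadjusted p under 0.05. A period of 12 h gave 266, 14 h gave 61, 16 h gave 136, 18 h gave 50, 20 h gave 61 and 22 h gave 53. A period of 26 h gave 130, 28 h gave 149, 30 h gave 119, 32 h gave 96, 34 h gave 82 and 36 h gave 77.

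**Figure D2:**
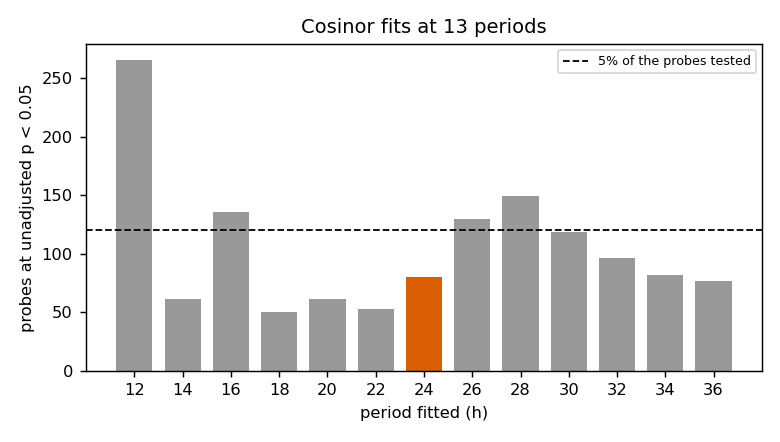
Number of probes at an unadjusted p under 0.05 (vertical axis) for cosine fits at 13 periods in hours (horizontal axis), with a dashed line at 5% of the probes tested. The 24 h bar stands at 80, below the line at 120.6, and the 12 h bar at 266.

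The comparison of the first with the second 12 h of a cycle asked whether transcripts followed the former alternation of light and darkness as a step. No gene differed past the threshold. Genes of histidine synthesis (hisB), glycolysis (eno, enolase), lysyl-tRNA formation (lysS) and aspartate-derived amino acid synthesis (asd), together with surE, came closest, all with higher levels in the second 12 h. The fitted differences of the light genes were smaller than their standard errors, except for htr1, so larger differences are not excluded.

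By limma 0 of 2412 probes passed the threshold, 175 had an unadjusted p under 0.05 and the smallest adjusted p was 0.680. The difference, second minus first 12 h, was 0.26 ± 0.09 (log2, SE) for hisB, 0.27 ± 0.10 for eno, 0.35 ± 0.14 for lysS, 0.18 ± 0.07 for asd and 0.24 ± 0.10 for surE, each with an adjusted p of 0.680. For hisB, eno, lysS and asd 8 of the 9 later values lay above the mean of the earlier ones, and for surE all 9 did. The difference was -0.13 ± 0.08 for htr1, -0.07 ± 0.08 for sop1, 0.07 ± 0.13 for hop, -0.02 ± 0.06 for sop2, -0.01 ± 0.10 for htr2 and -0.01 ± 0.17 for bat, with adjusted p between 0.795 and 0.997. The signs for hop, sop2, htr2 and bat changed under other processing choices. In simulated data the test recovered a share of 0.18 of probes with a difference of 0.25, a share of 0.82 with 0.50 and all with 1 or 2.

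The comparison of cycle 3 with cycle 1 asked how transcripts shifted between the first day and the third day in darkness. In cycle 3 the transducer gene htr1, the threonyl-tRNA synthetase gene thrS, cobN (cobalamin synthesis), arcA (arginine deiminase) and nadA (NAD synthesis) were higher, and hop and glpK (glycerol kinase) were lower. None of these named genes passed the threshold over all probes, and 6 probes without a symbol did. Ranges of array numbers, which may be batches, followed the cycles, as given after the values.

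By limma 6 of 2412 probes passed, 1 higher and 5 lower in cycle 3, and 286 had an unadjusted p under 0.05. This count was not stable: it was 150 without replicate 1, 0 without replicate 2, 1 from the deposited table or with saturated spots left out, and 2 for 11 of the 18 time points left out singly. The higher probe, 3259, rose by 0.47 ± 0.07 (log2, SE, adjusted p 0.00775). Of the lower ones, probe 1659 fell by 0.69 ± 0.14 (adjusted p 0.0429), with -0.71 on replicate 1 and -0.67 on replicate 2 arrays. Probe 711 fell by 0.83 ± 0.13 (adjusted p 0.00775), a difference carried by replicate 2 arrays alone, with -1.66 there and -0.0087 on replicate 1 arrays. These IDs were picked after their values were seen. The smallest adjusted p of a named gene was 0.153. The differences were 0.37 ± 0.10 for thrS and 0.32 ± 0.09 for htr1 (adjusted p 0.153 for both), 0.26 ± 0.08 for cobN (adjusted p 0.180), 0.26 ± 0.08 for arcA (adjusted p 0.207) and 0.52 ± 0.16 for nadA (adjusted p 0.212). For each of these 5 genes all 6 values of cycle 3 lay above the mean of cycle 1. Without background correction thrS, htr1 and cobN passed, and with the time point as a random block htr1, cobN and arcA did. The sample signal of nadA lay above background on 13 of 36 arrays, and with the pattern of blank spots as a block the difference of arcA was -0.020.

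The mean of hop was 0.67 ± 0.30 (log2 to reference, SD, n = 6 time points) in cycle 1 and 0.24 ± 0.17 in cycle 3, a difference of -0.43 ± 0.15 (SE, adjusted p 0.260) with all 6 later values below the earlier mean. The mean of glpK was 0.59 ± 0.72 in cycle 1 and -0.22 ± 0.16 in cycle 3, a difference of -0.81 ± 0.28 (adjusted p 0.244). With the range of array numbers as a block both differences changed sign, to 0.16 for hop and 0.44 for glpK. The difference was 0.21 ± 0.11 for htr2, 0.15 ± 0.08 for sop2, 0.11 ± 0.09 for sop1 and -0.11 ± 0.18 for bat, with adjusted p between 0.469 and 0.871, and that of bat was 0.37 with the range block. In simulated data the test recovered a share of 0.32 of probes with a difference of 0.25, a share of 0.58 with 0.50 and all with 1 or 2.

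The comparison of cycle 2 with cycle 1 asked how transcripts differed between the second and the first day in darkness. The protein export gene secY and the cobalamin genes cbiT and cobN were higher in cycle 2, as was dcd (deoxycytidine triphosphate deaminase), while the transducer gene htr7 was lower. None of them passed the threshold. By limma 3 probes without a symbol did, 2 higher and 1 lower, and 394 had an unadjusted p under 0.05. Probe 2511 rose by 1.21 ± 0.19 (log2, SE, adjusted p 0.0155). The differences were 0.33 ± 0.11 for secY (adjusted p 0.179), 0.44 ± 0.15 for cbiT (0.183), 0.21 ± 0.08 for cobN (0.217), -0.28 ± 0.10 for htr7 (0.217) and 0.57 ± 0.22 for dcd (0.235). The 6 values of cycle 2 lay above the cycle 1 mean for each of the higher genes and below it for htr7. The sample signal of dcd lay above background on 14 of 36 arrays. From the deposited value table htr7 and dcd had the opposite sign. The differences were -0.36 ± 0.15 for hop, -0.38 ± 0.18 for bat, 0.22 ± 0.11 for htr2, 0.10 ± 0.08 for sop2, 0.10 ± 0.09 for htr1 and 0.06 ± 0.09 for sop1, with adjusted p between 0.261 and 0.772. The sign for bat was opposite from the deposited table and that for htr1 with normalization by print grid. With the range of array numbers as a block htr2 passed (0.47, adjusted p 0.0345), and with the pattern of blank spots as a block htr2 (0.34) and secY (0.37) did, each with an adjusted p of 0.0464. The count hung on single time points and on the replicate. It was 152 without 16 h, with cbiT and dcd among the probes, 16 without 0 h, 14 without 24 h and 0 without 8, 32, 36 or 44 h, so that probe 2511 was no longer called. It was 70 without replicate 1 and 0 without replicate 2.

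Between cycle 2 and cycle 3 the tryptophan synthesis gene trpC came closest to the threshold, with a higher level in cycle 3. The single genes ppsA (phosphoenolpyruvate synthase), hisD (histidine synthesis), hemL (haem synthesis) and phoU (phosphate regulation) were also higher in cycle 3, while eno was lower. No gene passed the threshold, though trpC and htr1 each did under an alternative given below. By limma 0 of 2412 probes passed, 372 had an unadjusted p under 0.05 and the smallest adjusted p was 0.104. The count was 30 with the range of array numbers as a block. The difference was 0.84 ± 0.19 (log2, SE) for trpC (adjusted p 0.135) and 0.37 ± 0.11 for ppsA (0.192). It was 0.60 ± 0.19 for hisD (0.198), 0.54 ± 0.17 for hemL (0.208), 0.41 ± 0.13 for phoU (0.216) and -0.29 ± 0.11 for eno (0.260). Most of the rise came from replicate 1 arrays: on replicate 1 and replicate 2 arrays it was 1.26 and 0.42 for trpC, 0.73 and 0.0045 for ppsA, 1.07 and 0.13 for hisD, 0.87 and 0.20 for hemL and 0.60 and 0.22 for phoU. With the range block the difference of trpC was 0.98 (adjusted p 0.0311), and without background correction htr1 passed (0.29, adjusted p 0.0375). All 6 values of cycle 3 lay above the cycle 2 mean for trpC, hisD, hemL and phoU, and 5 of 6 did for ppsA. The sample signal of trpC lay above background on 6 arrays of cycle 2 and 12 of cycle 3. For hisD and for hemL it did so on 6 and 11 arrays, and for ppsA and phoU on 12 in both cycles. The cycle 2 levels of trpC, hisD and hemL thus rest partly on signal at background, which limits their differences. The sign for phoU was opposite without background correction and from the deposited table. The differences were 0.23 ± 0.09 for htr1, 0.27 ± 0.18 for bat, 0.05 ± 0.08 for sop2, -0.08 ± 0.15 for hop, 0.04 ± 0.09 for sop1 and -0.01 ± 0.11 for htr2, with adjusted p between 0.267 and 0.965. The signs for hop, sop1 and htr2 changed under other processing choices.

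Array numbers in the labels form 5 ranges, and these followed the cycles. The labels do not say whether the arrays of a range were printed or hybridised together, so taking a range as an array batch is an assumption. On replicate 2 arrays cycle 1 lay in range 2, except for the array at 16 h in range 4, cycle 2 lay in range 3 and cycle 3 in range 5. On replicate 1 arrays cycle 1 lay in ranges 1 and 4, cycle 2 in ranges 1 and 2 and cycle 3 in ranges 3 and 4. Within range 4 and replicate 1, where 4 arrays of cycle 3 met 2 of cycle 1, limma called 1 probe, which was not among the 6 called over all arrays, and 101 had an unadjusted p under 0.05. Those 6 kept their direction there, each with an adjusted p of 0.919. The arrays of this range are part of those that gave the 6 calls, so the shared direction is partly built in. Fits within a range had no 24 h terms. Within range 1 and replicate 1, where 2 arrays of cycle 2 met 4 of cycle 1, 0 probes were called and 47 had an unadjusted p under 0.05. No other range and replicate held arrays of both cycles of a comparison, and none held arrays of cycles 2 and 3 together. With all 36 arrays and the range as a block, 21 probes passed between cycle 3 and cycle 1, and 3 of these were among the 6.

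A further comparison asked whether a 24 h course kept its size and timing over the 3 cycles. No named gene changed its course past the threshold. The closest were glpK, the excision repair gene uvrB, msrA (methionine sulfoxide reductase), hutI (histidine use) and pheS (phenylalanyl-tRNA synthetase). Among these, glpK was high from 8 to 16 h, with 1.40 (log2 to reference) at 12 h, and stayed at or below -0.06 from 32 h on. By limma 3 of 2412 probes passed, none with a symbol, and 182 had an unadjusted p under 0.05. The count ran from 0 to 7 with a time point left out. On the arrays of either replicate alone 0 passed, and with median centring glpK passed (adjusted p 0.0141). The adjusted p was 0.174 for glpK, 0.232 for uvrB, 0.316 for msrA and 0.342 for hutI and pheS. For hop, bat, sop1, sop2, htr1 and htr2 it lay between 0.756 and 1.00. In simulated data with a wave in cycle 1 only, the test recovered none of the probes with an amplitude of 0.25, a share of 0.12 with 0.50, of 0.76 with 1 and of 0.96 with 2.

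Some genes varied between time points by more than their dye-flip arrays differed. They were rpl12p and rpmC (ribosomal proteins), eno, the transducer gene htr8, arcC (carbamate kinase), secY and trpB (tryptophan synthase). This comparison took all 36 arrays as values, so it measured how far the technical repeats agree and is not a test of the culture. Of these, rpl12p, rpmC, eno, secY and htr8 were low at 0, 8 and 56 h, and rpl12p, rpmC and htr8 again at 68.5 h, and no shared function of them was tested. Other bright probes varied along the same course, in both directions. Among the other 599 probes of the brightest 25%, the first principal component held 44.3% of the variance over time points. With its sign, which is arbitrary, set to match, it followed the mean profile of the 7 genes, with a Pearson r of 0.932 over 18 time points (permutation p 1e-05, the smallest possible) and a Spearman rho of 0.866 (permutation p 2e-05). Without the 2 time points farthest from the component's median r was 0.908. Of the 599 probes 20.4% had an r of at least 0.6 with the profile and 15% an r of at most -0.6. Loess had centred the log ratios at each intensity, so these shares cannot show whether the bright probes dropped as a group.

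By limma 157 of 2412 probes passed, 7 of them named, and 467 had an unadjusted p under 0.05. Under the processing alternatives the count ran from 76, with saturated spots left out, to 232, with the brighter 50% of probes. The adjusted p was 8.38e-05 for rpl12p, 0.000407 for rpmC, 0.00135 for eno, 0.00539 for htr8, 0.0158 for arcC, 0.0172 for secY and 0.0471 for trpB. The level of rpl12p ran from -1.20 (log2 to reference) at 68.5 h to 0.20 at 16 h and that of rpmC from -1.13 at 8 h to 0.56 at 36 h. The level of eno ran from -0.59 at 56 h to 0.32 at 16 h, that of htr8 from -0.12 at 8 h to 1.12 at 16 h, that of arcC from -0.42 at 8 h to 0.61 at 52 h and that of secY from -0.89 at 8 h to 0.05 at 44 h. For trpB it reached 1.73 at 48 h and 1.63 at 52 h, against at most 0.33 elsewhere, and its call was lost under 7 of the 9 other processing choices run for it. From the deposited table htr8, arcC, rpmC and trpB did not pass, and of the 7 genes rpl12p alone passed under every alternative run. The sample signal of trpB lay above background on 18 of 36 arrays. The adjusted p of hop was 0.205, that of htr2 0.282, those of bat and htr1 0.298, that of sop1 0.448 and that of sop2 0.901.

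**Figure D3:**
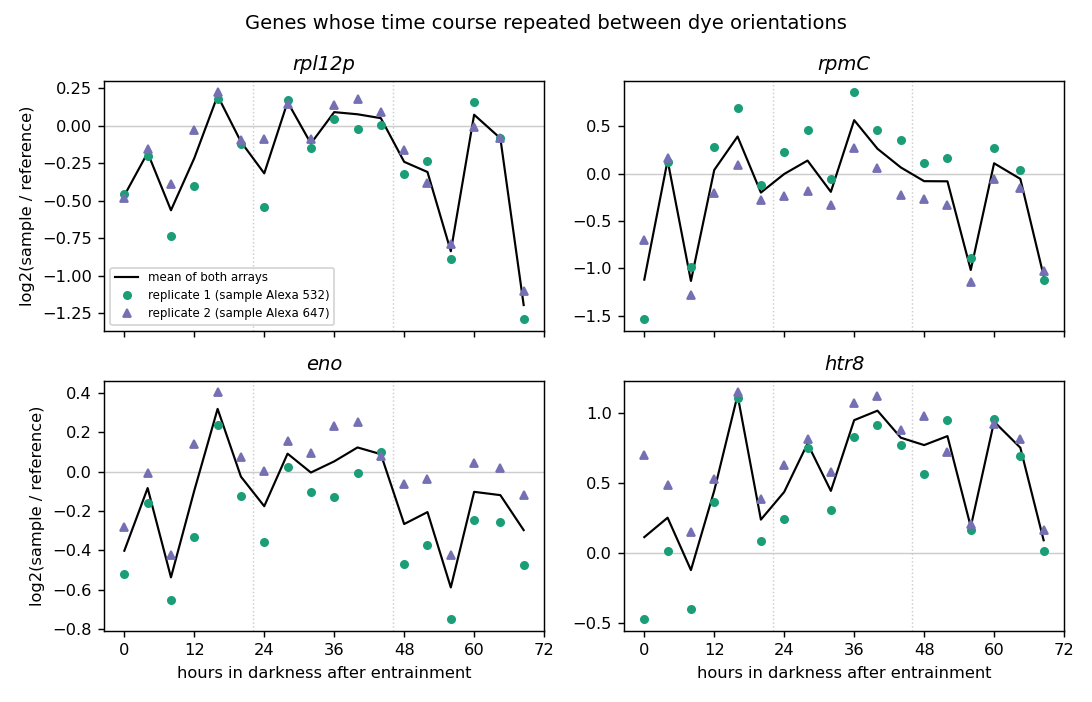
The log2 ratio of sample over reference (vertical axes) against hours in darkness (horizontal axes) for rpl12p, rpmC, eno and htr8, which varied between time points beyond their dye-flip arrays, with both replicates as points and their mean as a line. The mean of rpl12p is lowest at 68.5 h, at -1.20, and that of rpmC at 8 h, at -1.13.

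**Figure D4:**
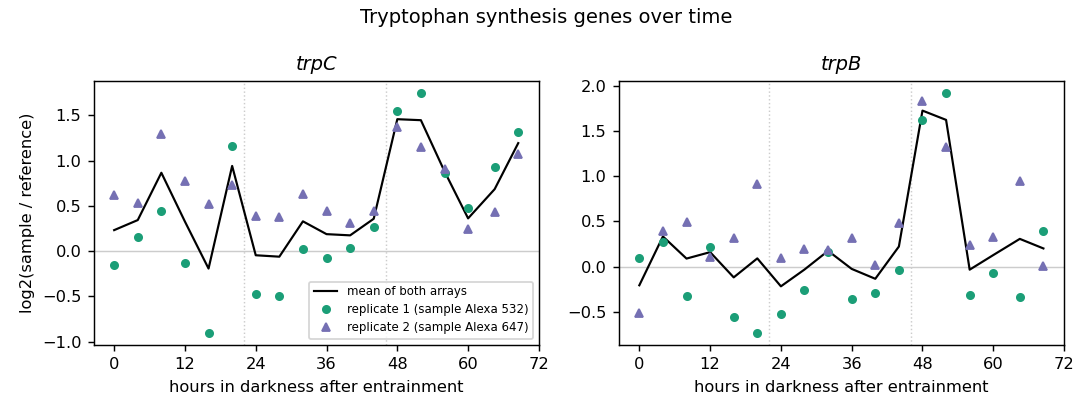
The log2 ratio of sample over reference (vertical axes) against hours in darkness (horizontal axes) for trpC and trpB, with both replicates as points and their mean as a line. The means at 48 and 52 h are 1.46 and 1.45 for trpC and 1.73 and 1.63 for trpB.

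Gene lists asked whether genes of a shared function moved together. No list passed in any of the comparisons. The closest were the transducer and chemotaxis genes and the amino acid synthesis genes, both higher in cycle 3 than in cycle 1. Of 32 lists fixed by symbol pattern, 11 had at least 4 measured members and were tested with limma's camera.

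Between cycle 3 and cycle 1 the median log2 difference was 0.13 for 11 chemotaxis genes (p 0.0277, adjusted p 0.189) and 0.13 for 10 amino acid synthesis genes (p 0.0344, adjusted p 0.189). With an estimated correlation between genes their adjusted p was 0.429, and no list passed with either correlation. The median was 0.11 for 4 cobalamin genes and 0.08 for a tRNA charging list of 14 genes, 12 synthetases with the amidotransferase genes gatA and gatC, each with an adjusted p of 0.379. It was 0.08 for 6 genes of the tricarboxylic acid cycle, 0.04 for 5 chaperone and proteasome genes, -0.012 for 4 replication genes and -0.0037 for the list of hop, sop1, sop2 and bat, with adjusted p between 0.574 and 0.901. Median and mean differed in sign for 3 lists: 4 repair genes had 0.0088 and -0.03, 4 sugar metabolism genes 0.02 and -0.14 and 9 purine and pyrimidine genes -0.02 and 0.03, each with an adjusted p of 0.901. The test pointed up for the repair list and the purine and pyrimidine list and down for the sugar list.

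Between cycle 3 and cycle 2 the amino acid synthesis list had a median of 0.11 (p 0.0239, adjusted p 0.262). The median of the sugar metabolism list, which holds ppsA and eno, was -0.068 (adjusted p 0.928). Adjusted p was at least 0.631 between cycle 2 and cycle 1 and was 0.837 for every list between the first and second 12 h. Adjusted over the list alone, single genes passed between cycle 3 and cycle 1 in 5 lists, against 0 over all genes tested: htr1, cobN, hop, glpK and thrS. Between cycle 2 and cycle 1 cbiT and cobN did, and between cycle 3 and cycle 2 trpC, hisD, ppsA and eno did. For the 24 h course and the first against the second 12 h this count was 0 in every list.

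For the 24 h course no list had a gene past the threshold, so no share of called genes was tested. Median amplitudes ran from 0.055 for the tricarboxylic acid cycle list to 0.17 for the sugar metabolism list. Peak times of the 4 cobalamin genes lay closest together, around 21.2 h with a mean resultant length of 0.885 on a scale from 0 to 1 (permutation p 0.0343, adjusted p 0.377 over 11 lists). For the other lists the mean resultant length lay between 0.095 and 0.478, with adjusted p of at least 0.821.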

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

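The comparison of both dye orientations for bat and htr2 was chosen after the result was seen, and the other tests of this part before. In each of 30 groups, made of the 6 time points of a cycle for 10 genes, the highest and the lowest value were set against the others. Chance marks about 1 in 20 such groups, and 2 of the 30 were marked.

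The bacterio-opsin activator gene bat stood at 0.455 (log2 to reference) at 28 h, in cycle 2, where its other 5 values lay between -0.26 and -0.0098. It was marked because a single time point lay far from the others. The arrays disagree on it: on replicate 1 the value was 0.574 against -0.767 to -0.369, and on replicate 2 it was 0.336, inside the range of the others from 0.209 to 0.644. The sensory transducer gene htr2 stood at -0.316 at 44 h, in the same cycle, where its other values lay between 0.086 and 0.206. It lay below the others on both replicates, at -0.551 against 0.00899 to 0.141 and at -0.0814 against 0.069 to 0.271. The gap to the nearest value took a share of 0.65 of the range for bat and 0.77 for htr2. No explanation was tested for either value.

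For 3 genes the 24 h course differed between the cycles by limma's interaction test, which marked them as a difference between groups. None of them has a symbol. Of 100 groupings of the 18 time points, 2 gave as many genes, the real one included, which is a share under 0.05, and the highest other count was 4. This share was not adjusted over the comparisons that were regrouped, and successive samples of a single culture may be correlated, so chance was not excluded. The count did not hold up: it was 0 without replicate 1, 0 without replicate 2, 0 with the array range as a block and 0 with 10 of the 18 time points left out singly.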

How the results depend on the processing

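The alternatives with the high scan only, with saturated spots left out, with blank probes kept, with loess by print grid, with the brighter 50% of probes and with the pattern of blank spots as a block, and the contrasts within a range of array numbers, were chosen after the data were seen. The count of genes with a 24 h course was 0 under all 20 processing alternatives and with each time point left out in turn. The probes at an unadjusted p under 0.05 numbered 27 to 145 under those that kept the 24 h period, and 61 and 149 when the period was set to 20 and 28 h. All 413 values of named genes in that test kept their side of the threshold. The count for the first against the second 12 h was also 0 under its 17 alternatives and with each time point left out. Gene lists had no call on the 24 h course under any alternative run. On the other contrasts 1 list passed without background correction, without replicate 1 and without replicate 2, and 0 with each time point left out. For the changes below the cause was not tested, except where fewer probes or arrays were used.

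Between cycle 3 and cycle 1 the count of 6 became 18 without background correction, 1 from the deposited table, 2 with the high scan only, 1 with saturated spots left out, 34 with arrays as values and the time point as a random block, 21 with the array range as a block, 2 with a trended robust prior and 12 with a linear slope. Between cycle 2 and cycle 1 the count of 3 became 15 without background correction, 11 with median centring, 7 from the deposited table, 6 with the high scan only, 1 without the dimmest 25% of genes, 0 with the brighter 50% of probes, 6 with the random block, 21 with the range block, 41 with the blank pattern block and 11 without the 24 h terms. The count of 0 between cycle 3 and cycle 2 became 14 without background correction, 3 from the deposited table, 30 with the range block and 17 with the blank pattern block. Genes with a changed 24 h course numbered 5 with median centring, 1 without the dimmest 25% of genes and 1 with the brighter 50%. They numbered 0 without background correction, from the deposited table, with loess by print grid and with each of the 3 blocks. Genes varying between time points fell from 157 to 76 with saturated spots left out, numbered at most 232 under the other processing alternatives, with the brighter 50% of probes, and lay between 116 and 170 with a time point left out.

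With a replicate or a time point left out, the count between cycle 3 and cycle 1 ranged from 0 without replicate 2 to 150 without replicate 1. It was 2 without any of the time points at 4, 12, 20, 32, 36, 40, 44, 48, 52, 60 or 64.5 h, 3 without 68.5 h and 11 without 16 h. Between cycle 2 and cycle 1 it ranged from 0 to 152. It was 70 without replicate 1, 0 without replicate 2, 152 without 16 h, 16 without 0 h, 14 without 24 h, 8 without 68.5 h, 7 without 28 h, 5 without 56 h, 1 without 4 or 20 h and 0 without 8, 32, 36 or 44 h. For cycle 3 against cycle 2 it ranged from 0 to 6, the latter without replicate 1, and was 2 without 16 or 20 h. For the changed 24 h course it ranged from 0 to 7. It was 7 without 44 h, 2 without 16 h, 3 without 20 or 32 h, 1 without 4, 8, 60 or 68.5 h and 0 without any other time point.

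Some named genes reversed. Between the first and second 12 h, without background correction, from the deposited table, with loess by print grid and without a drift term, hop was at -0.0544, -0.00457, -0.0574 and -0.0376 and sop2 at 0.0167, 0.0212, 0.0291 and 0.0157. In the same contrast htr2 was at 0.0239 with median centring, 0.0443 from the deposited table, 0.00626 with the blank pattern block and 0.0365 without drift, and bat at 0.00129 with the high scan only, 0.0179 with the range block and 0.11 with the blank pattern block. With a time point or replicate left out, bat ranged from -0.128 to 0.0593, sop2 from -0.0748 to 0.0293 and htr2 from -0.0766 to 0.0537.

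Between cycle 3 and cycle 1, without background correction, from the deposited table, with the range block and with the blank pattern block, bat was at 0.049, 0.146, 0.365 and 0.0521 and htr7 at 0.00656, 0.0521, 0.302 and 0.0978. The gene orc7 was at 0.0313 without background correction, 0.0219 with median centring, 0.0607 from the deposited table and 0.132 with the range block, cbiT was at -0.0406 without background correction and psmB at -0.00326 with loess by print grid. With the range block and the blank pattern block, hop was at 0.155 and 0.195, glpK at 0.438 and 0.468, uvrB at 0.749 and 0.575, gyrA at 0.591 and 0.465 and pyrB at -0.0186 and -0.0838. With the range block sdhC was at -0.0148 and leuS at -0.0236, and with the blank pattern block arcA was at -0.0199. With a time point or replicate left out ppsA ranged from -0.0108 to 0.419, psmB from -0.0331 to 0.268, orc7 from -0.183 to 0.146 and cbiT from -0.0346 to 0.364.

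Between cycle 2 and cycle 1 the deposited table gave 0.0996 for htr7, -0.0864 for dcd and 0.0558 for bat, and loess by print grid gave -0.0933 for htr1, which ranged from -0.0178 to 0.211 with a time point or replicate left out. For cycle 3 against cycle 2 phoU was at -0.0443 without background correction and -0.0983 from the deposited table. In that contrast htr2 was at 0.0888 without background correction, 0.0566 with loess by print grid and 0.0619 with the range block, and hop at 0.0267 with loess by print grid, 0.386 with the range block and 0.427 with the blank pattern block. With a time point or replicate left out hop ranged from -0.178 to 0.0199, sop1 from -0.00489 to 0.084 and htr2 from -0.0966 to 0.0346.

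Some calls of named genes changed too. In the contrast of cycle 3 with cycle 1 htr1 passed without background correction (adjusted p 0.0193, and 0.0386 with the random block), with a range of 0.0193 to 0.591 over the processing alternatives. Without background correction thrS (0.049) and cobN (0.0491) passed too, and so did cobN (0.0275) and arcA (0.0386) with the random block. For cycle 2 against cycle 1 htr2 passed with the range block (0.0345) and, with secY, with the blank pattern block (0.0464 for both). For cycle 3 against cycle 2 trpC passed with the range block (0.0311) and htr1 without background correction (0.0375). The changed 24 h course of glpK passed with median centring (0.0141) and that of pheS without 44 h (0.025). Without replicate 1, arcA (0.021) and htr7 (0.0398) passed between cycle 3 and cycle 1 and htr7 (0.04) between cycle 2 and cycle 1, where cbiT (0.0273) and dcd (0.0217) passed without 16 h. Of the 909 gene-by-setting values between cycle 3 and cycle 1 863 kept direction and side, 8 newly passed and 38 reversed. For variation between time points 30 of 195 values no longer passed. From the deposited table htr8, arcC, rpmC and trpB did not pass (adjusted p 0.0652, 0.202, 0.0805 and 0.64), and with median centring arcC, eno and trpB did not (0.15, 0.0807 and 0.127). Also among these were arcC and secY without 8 h (adjusted p 0.15 and 0.233) and trpB without 48 h (0.304) or 52 h (0.172). Every ratio uses both dyes, so weak Alexa 532 signal, above background for 28.9% to 96.2% of probes depending on the array, limits dim probes on both replicates.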

Other observations

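The tests of array batches for trpB and for trpC, of a 24 h course for 7 varying genes and of the share in the brightest 25% of probes against all probes there were chosen after the result was seen, as were the genes in the first paragraph and the patterns weighed below. The genes for breakdown of histidine had the highest means above the reference among the named genes, though other genes stood above them at single time points. The mean over 18 time points was 1.34 ± 0.26 (log2 to reference, SD) for hutG, 1.00 ± 0.44 for hutU and 0.95 ± 0.45 for hutI, and each lay above the reference at 18 of 18 time points. On replicate 1 and replicate 2 arrays the means were 1.25 and 1.42 for hutG, 0.71 and 1.28 for hutU and 0.72 and 1.18 for hutI. The phosphate regulator gene phoU stood lowest, at -1.48 ± 0.30, with -1.98 on replicate 1 and -0.98 on replicate 2 arrays. Of the 133 named genes 23 stood below the reference at all 18 time points and 8 above it. Among the former were 4 of the 6 measured genes of the tricarboxylic acid cycle, with -0.66 ± 0.10 for sucC, -0.61 ± 0.14 for sucD, -0.79 ± 0.26 for mdh and -0.63 ± 0.23 for citZ. Their means on replicate 1 and replicate 2 arrays were -0.67 and -0.65 for sucC and -0.50 and -0.73 for sucD. They differed more for mdh, with -1.13 and -0.44, and for citZ, with -1.07 and -0.19. The other 2 genes lay closer to the reference, with -0.17 ± 0.09 for sdhC and -0.018 ± 0.10 for icd, and no test compared the level of this list with other genes. The reference was a mid-log culture and not a sample of this series, so these levels do not separate the effect of darkness from that of growth.

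The genes rpl12p, rpmC, eno, htr8, arcC, secY and trpB varied between time points on both dye orientations. With the range of array numbers as a block 6 of the 7 stayed past the threshold, which argues against array batches as the whole cause for these 6. For trpB the block ended the call, with an adjusted p of 0.140 against 0.0471, as its F fell from 3.73 to 2.85. The 24 h terms took 4.71% of the variance that linear time left in the mean profile of the 7 genes. This share cannot decide on a daily course, since 24 h courses with opposite peaks partly cancel in a mean. Fitted peaks lay between 14.61 h and 17.03 h for rpl12p, rpmC, htr8, eno and secY. They lay at 1.819 h for arcC and 2.71 h for trpB. Taken singly, none of the 7 genes had a 24 h course past the threshold (limma's F-test, adjusted p 0.993 for each). The profile had a correlation of -0.309 with the mean log2 intensity of a time point over 18 time points (permutation p 0.215). Spearman's rho was -0.271 (permutation p 0.275), and r was -0.304 without the 2 time points farthest from the median intensity. This lay between the bounds set, so overall signal cannot be told apart from other causes. A difference in RNA or labelling between time points may also apply, since both arrays of a time point share the same RNA, and no test here separates it from a change of the culture.

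The tryptophan synthesis genes trpB and trpC were high at 48 and 52 h. In the annotation of strain 91-R6 these genes are neighbours. The mean of trpB at 48 and 52 h lay 1.60 (log2) above that at 56 and 68.5 h, whose arrays came from the same ranges. The level of trpB was thus not high throughout these ranges. Since 48 and 52 h were picked for their high values, this difference is no independent test of array batches. With the array range as a block over all 36 arrays the call of trpB ended, so array batches are not excluded for it. For trpC the difference between these time points was 0.414, between the bounds set, so array batches cannot be told apart from other causes for trpC. Of the 8 array values at 48 and 52 h, 7 lay more than 2 SD above the mean of the other time points for that gene and dye orientation. Since the genes and times were picked for these values, this count decides nothing, and noise of dim probes stays open. A change of the culture stays open too and was not tested.

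On replicate 2 arrays alone 150 probes differed between cycle 3 and cycle 1, against 0 on replicate 1 arrays alone. Of the 150, 40% (60 probes) had the same direction on replicate 1 arrays, against 44.6% of all probes. This share lay within the bound set for array batches that follow the cycles. The share of all probes lay within it too, so it cannot tell batches apart from other causes. In the direction of the replicate 2 change, the median log2 difference of the 150 was -0.121 on replicate 1 arrays, against 0.55 on replicate 2 arrays. Noise independent between probes would favour neither direction on replicate 1 arrays, so it does not by itself give this opposite median. Of the 10 that lay in the brightest 25% of probes, 90% (9 probes) had the same direction, against 65.7% of all probes there (exact binomial p 0.18, two-sided). These 10 probes are too few to tell a weak Alexa 532 signal on replicate 1 arrays apart from other causes. In cycle 1 the Alexa 532 channel was weak on both replicates, with 28.9% to 70.4% of probes above background on replicate 1 arrays and 35.6% to 66.1% on replicate 2 arrays. In cycle 3 these shares rose to 55.1% to 96.2% and 76.1% to 91.3%. On replicate 2 arrays this dye carries the reference and on replicate 1 arrays the sample. A shift of its signal between cycles would thus have opposite directions on the replicates. Such a shift was not excluded for the 150 probes, of which 23.3% were higher in cycle 3. Array batches, a weak Alexa 532 signal and such a shift all stay open. A change of the culture over the days in darkness stays open as well and was not separated from the batches.

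Other groupings of the 18 time points were drawn 100 times for each comparison, the real one included. For the 24 h course 54 groupings gave as many probes at an unadjusted p under 0.05 as the real 80. The other groupings had a median of 82 and a highest count of 385. For the first against the second 12 h 27 groupings gave as many as the real 175, with a median of 91 and a highest other of 713. Between cycle 3 and cycle 1, 5 groupings gave as many calls as the real 6, with a highest other of 150. Chance was not excluded for these 3 comparisons. Between cycle 2 and cycle 1 only the real grouping, 1 of 100, gave 3 calls, with a highest other of 1. For cycle 3 against cycle 2 only the real one, 1 of 100, gave 372 probes at an unadjusted p under 0.05. The others had a median of 93 and a highest count of 348. These shares were not adjusted over the comparisons. The count used, calls or probes at an unadjusted p under 0.05, depended on whether the real grouping gave a call. Chance was therefore not excluded for these comparisons either, even among freely exchanged time points. The cycles are runs of successive samples of a single culture, which may be correlated in time, and they follow the ranges of array numbers. Neither correlation in time nor array batches are excluded. The count between cycle 2 and cycle 1 was 0 without 8 h and 152 without 16 h. Random groupings thus reached 150 calls or 713 probes, several times the real counts. A structure of the samples that the cycles and the 12 h parts do not describe may apply, and this was not tested.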
